A study of Mus musculus with 10 samples.

How the data were processed

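Lumbar motor neurons of 10 mice, 5 HSA-NRTN and 5 wild-type littermates, were captured by laser microdissection as pools of about 50 cells, and each pool gave 1 Smart-seq2 library fragmented with Tn5, per the labels' protocols. This kit amplifies whole transcripts by PCR without molecular identifiers and does not mark strand, so reads of a gene and of an antisense or overlapping partner are not separated by strand. Group and sex were taken from the labels. Replicate numbers follow the order of the records and pair no animals across the groups.

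The authors aligned reads with STAR 2.5.0a and counted them per gene with HTSeq on GRCm38.p6, per the submitters' processing notes, and the annotation release and counting settings are not given in the sources used here. The deposited count files hold raw counts for 51912 genes, 92 ERCC spike-in sequences and 5 tally entries that name no gene. Of all reads in these files, 13.5% to 42.3% per library were counted to genes, 16.3% to 58.6% were not aligned, 5.69% to 12.1% fell on no feature, 15.3% to 32.5% were not uniquely aligned and 0.737% to 2.12% were ambiguous. Tally entries and spike-ins stayed out of library sizes and tests. Spike-in counts were 0.0336% to 4.86% of gene and spike-in counts.

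A deposited expression table holds a signal made by the authors by dividing the counts of each library by 1 DESeq2 size factor, for 18754 features with at least 11 counts over all libraries. The ratio of that signal to the counts was constant within each library, to a relative spread of 9.71e-15. A deposited comparison table gives the authors' log2 fold changes with their standard errors, a Wald statistic as a score, and p-values with and without adjustment, from DESeq2 per the submitters' processing notes, with no version or design given in the sources used here. The log2 values are moderated. The authors' fold changes were used only for comparison.

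Symbols came from the deposited tables for 18698 genes and from the reference for 32976, while 238 genes had none. Coordinates are those of GENCODE M21 on GRCm38, which held 51633 of the 51912 gene identifiers.

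Counts were analysed in R 4.3.3. Genes were kept by edgeR's filterByExpr for the genotype groups, which left 11630, and libraries were scaled by TMM. Genotype was tested with the quasi-likelihood F test of edgeR 4.0.16 at its default settings with no covariate, sex with genotype in the model, and the genotype by sex interaction with both. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. The common biological coefficient of variation was 0.595. Levels are given in CPM with library sizes scaled by TMM, as mean ± SD. Standard errors of log2 fold changes were taken from the F statistic. Groups of genes were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, for the 31 lists with at least 4 measured members, two-sided and adjusted over these lists. Another 9 lists were too small, and the panel and the sex-linked genes were not tested as lists. List members were also adjusted over the list alone. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance one way or, in its mixed form, change in either direction, were run beside it.

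Design, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule took genes with a conventional symbol and at least 10 counts in at least 4 of the 5 libraries of the higher group: the 12 largest changes per direction among called genes and, where fewer were called, those of smallest p until 8 were named per direction, given as values that did not pass. A panel of 15 genes was named whatever its values, and up to 4 members of smallest p per described list, here limited to members with an unadjusted p under 0.05. Outside the rule, Kcng4, Kcnn2, Dlk1, Uts2b, Htr1f, Htr1d, Npas1, Wnt7a, Sst, Ttr, Sln, Pter, Acpp, Ppp1r26, Lum, Gad2, Slc6a5 and the marker genes given by level in 1 library were named after their values were seen.

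For a gene with 0 counts in a group, a fold is a lower bound against a floor of 3 counts over that group, 0.130 CPM in wild-type and 0.138 CPM in HSA-NRTN libraries. With 1 to 3 counts the ratio of pooled counts is given with an exact 95% interval. Library quality was compared by exact two-sided permutation tests. The depth of 1875971 to 6641695 gene counts from about 50 cells leaves low genes to chance sampling of molecules, and 26070 genes had at least 1 count in any library.

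The tests were checked on simulated counts with the means, spread and library sizes of the 11630 genes, of which 200 were changed. For genotype, edgeR recovered 8.96% of 2-fold, 49.3% of 4-fold and 66.7% of 8-fold changes, and 8 of 91 calls were false (8.79%). In the same data 22.6% of 133 DESeq2 calls and 2.63% of 76 limma voom calls were false. For sex the recovered shares were 4.48%, 40.3% and 60.6%, and for the interaction 0%, 0% and 15.2%. Camera called both shifted lists of a simulation and none of the others. The simulated genes were drawn independently, so this does not check false list calls from genes that vary together across libraries.

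The alternatives tried were RLE and upper quartile factors, no filter beyond 1 count and a filter of 10 counts in 5 libraries, DESeq2 1.42.0 with its own filtering on all genes with a count, limma voom with and without sample quality weights, covariates for sex, for the runs of animal numbers (259 to 262 and 268 to 274) and for the number of genes detected, each sex alone, each library left out in turn and, for library quality, genes with at least 10 counts. Chosen after seeing the data were edgeR's newer adjusted-deviance fit, robust shrinkage, an adjusted p under 0.1, leaving out both libraries that stood apart (HSA-NRTN replicate 2 and wild-type replicate 1), a filter set for the sexes, DESeq2 on the genes kept by filterByExpr and the spike-in share as a quality measure. For other splits of the libraries, 100 were drawn, the real one included.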

Results

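Motor neurons were collected by laser capture from frozen sections of the lumbar spinal cord, as 1 pool per mouse, and the polyadenylated RNA of each pool was sequenced. Captured cells had a visible nucleolus and lay above a size minimum, so small motor neurons were left out by design. The 10 libraries came from 5 HSA-NRTN mice and 5 wild-type littermates, with 3 females and 2 males in each group, and each library stands for 1 animal. In HSA-NRTN mice the promoter of human skeletal actin drives neurturin, a ligand of the GDNF family, in muscle fibres. The transgene therefore acts outside the captured cells, and the neuronal level of Nrtn checks no label. Gene counts per library ran from 1875971 to 6641695, and 14090 to 19675 genes had at least 1 count. HSA-NRTN replicate 2 had the lowest gene count.

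The comparison of HSA-NRTN with wild-type pools asks, as the title of the series puts the theme, how neurturin secreted by muscle bears on the slow identity of motor neurons. Ptpro, a receptor-type protein tyrosine phosphatase, rose 10.1-fold, from 8.14 ± 2.32 CPM in wild-type to 82.6 ± 45.6 CPM in HSA-NRTN pools (SD, n = 5 each), and all 5 HSA-NRTN libraries lay above all wild-type libraries. Its log2 fold change was 3.33 (SE 0.42), with an adjusted p of 0.00928 in edgeR's quasi-likelihood test. Ptpro (ENSMUSG00000030223) lies on chromosome 6 of GRCm38 from 137252319 to 137463233. It was the single gene of 11630 tested that passed an adjusted p of 0.05, while 562 genes had an unadjusted p under 0.05, 280 higher and 282 lower. DESeq2, run with its own filtering on all genes with a count, called 126 genes, 96 higher and 30 lower. On the genes kept for edgeR, a setting chosen after seeing the data, DESeq2 called 59, 37 higher and 22 lower, and limma voom called 3, Chodl, Itm2a and Dkk3, all lower. The call of Ptpro ended without wild-type replicate 2 (adjusted p = 0.0656), without HSA-NRTN replicate 2 and wild-type replicate 1 together, the libraries least like the others (0.0607), with the 2 runs of animal numbers in the labels, which are not said to mark litters, as a covariate (0.0535), in females alone (0.214), in males alone (0.209), in limma voom (0.0628) and in limma voom with sample quality weights (0.187), while its log2 fold change lay between 2.83 and 3.81. Leaving out 1 library gave 13 called genes without HSA-NRTN replicate 3, 2 without HSA-NRTN replicate 1, HSA-NRTN replicate 2 or wild-type replicate 3, 0 without wild-type replicate 2 and 1 otherwise.

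A further 8 genes had an adjusted p of 0.0501 and so did not pass. Of these, Chodl, a lectin-like membrane protein used as a marker of fast motor neurons, lay between 408 and 1011 CPM in HSA-NRTN and between 1678 and 1937 CPM in wild-type pools (n = 5 each, log2 fold change -1.61, SE 0.25). Itm2a, an integral membrane protein, was at 223 ± 98.6 against 895 ± 239 CPM (SD, n = 5 each), and Plxdc1, a plexin domain protein, at 22.0 ± 7.89 against 84.0 ± 18.1 CPM. The secreted protein Dkk3 had a log2 fold change of -1.29 (SE 0.22), the transcription factor Maf was at 49.4 ± 15.0 against 168 ± 55.8 CPM, and Rspo2, a secreted activator of Wnt signalling, at 94.1 ± 34.5 against 313 ± 97.3 CPM. For each of these 6 genes, all 5 HSA-NRTN libraries lay below all wild-type libraries. In the other direction, Cacna2d1, an auxiliary subunit of voltage-gated calcium channels, was at 67.2 ± 46.7 against 4.89 ± 3.63 CPM. Hrk, a pro-apoptotic protein, had 147 counts over the HSA-NRTN libraries and 1 count over the wild-type libraries, a ratio of 155 with a 95% counting interval of 27.5 to 6181. HSA-NRTN replicate 2 held 62 of the 147 counts. The log2 fold change of Hrk, 7.18 with all libraries, ran from 6.07 to 8.47 with 1 library left out. Without HSA-NRTN replicate 3, 7 of these 8 genes passed, with adjusted p of 0.00204 for Chodl, 0.0195 for Itm2a and Cacna2d1, 0.0363 for Plxdc1 and Rspo2, 0.0373 for Hrk and 0.0452 for Maf. For each of these 7, that library lay nearest to the wild-type level among the 5 HSA-NRTN libraries. Leaving it out favours the calls, so these passes are no separate support. All 8 passed with robust shrinkage (0.0412 to 0.0456), with no filter beyond 1 count and in DESeq2. The adjusted-deviance fit of edgeR called 7 of them (0.0212 to 0.0267), all but Hrk. Of the 8, limma voom with sample quality weights called 6, the fit with the number of genes detected as a covariate 5 and that with sex as a covariate 4, while none passed with RLE or upper quartile factors, the stricter filter, the runs of animal numbers as a covariate or in 1 sex alone. Such intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

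**Figure D1:**
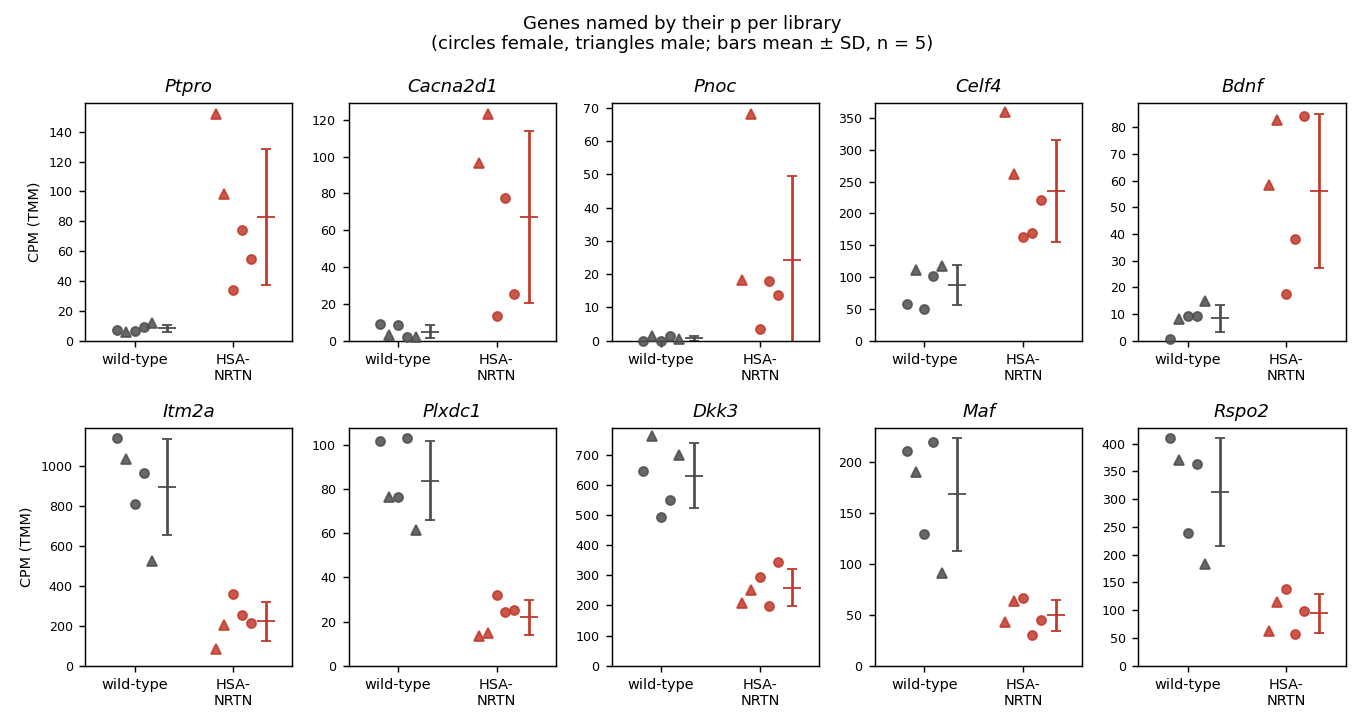
Level of 10 genes in each library, in CPM scaled by TMM, with wild-type libraries in grey and HSA-NRTN libraries in red, circles for females, triangles for males and bars for the mean ± SD (n = 5). Ptpro lies between 34.1 and 152 CPM in HSA-NRTN libraries and between 5.95 and 11.7 CPM in wild-type libraries.

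Among the genes next in order of p, none of which passed over all genes, Pnoc, which encodes the precursor of nociceptin, was at 24.3 ± 25.2 CPM in HSA-NRTN against 0.678 ± 0.700 CPM in wild-type pools (SD, n = 5 each), and passed without HSA-NRTN replicate 3 (adjusted p = 0.0452). Its log2 fold change of 5.09 was 4.23 without HSA-NRTN replicate 2. AA986860 had 224 against 4 counts, and the protease gene Ctso was at 31.3 ± 16.7 against 3.31 ± 2.13 CPM. The RNA-binding protein gene Celf4 was 2.69-fold and the extracellular matrix protein gene Crtac1 2.60-fold higher in HSA-NRTN pools. Calca, the gene of calcitonin gene-related peptide, was at 1138 ± 573 against 3677 ± 1466 CPM, and the anoctamin gene Ano3 at 98.0 ± 54.1 against 283 ± 57.8 CPM. The groups did not overlap for 145 genes, 1.25% of those tested, where chance gives 0.794%.

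Genes that mark fast motor neurons were lower as a group in HSA-NRTN pools. All 6 measured members of the list had a negative log2 fold change, with a median of -1.10 (camera, adjusted p = 2.54e-09), and the call held with an estimated correlation (adjusted p = 0.0368). None passed over all genes, and adjusted over the list alone 3 fell and 3 did not pass. Those that fell were Chodl, Calca and the potassium channel gene Kcnq5, the last at 4.16 ± 3.77 CPM in HSA-NRTN against 26.7 ± 11.7 CPM in wild-type pools (SD, n = 5 each), with 5 of 5 HSA-NRTN libraries below all wild-type libraries. Mmp9, a matrix metalloprotease of fast motor neurons, had a log2 fold change of -0.59 (SE 0.42), Kcnn2 one of -0.48 (SE 0.31) and Kcng4 one of -0.24 (SE 0.20). A further member, Dlk1, was too low to be fitted, at 3.75 ± 6.71 against 0.141 ± 0.315 CPM, the opposite direction.

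Genes that mark slow motor neurons were higher as a group. The 4 measured members had log2 fold changes of 0.56 (SE 0.69) for the nuclear receptor gene Esrrb, 0.63 (SE 0.26) for Esrrg of the same receptor family, 1.24 (SE 0.72) for the synaptic vesicle protein gene Sv2a and 1.82 (SE 0.91) for the potassium channel gene Kcnn3, with a median of 0.93. That of Kcnn3 was 2.96 without wild-type replicate 4, which lay at 20.3 CPM against 0 to 5.95 CPM in the other wild-type libraries, and 1.37 without HSA-NRTN replicate 1. Camera with its preset correlation called the list (adjusted p = 0.00281), but not with an estimated correlation (adjusted p = 0.270), nor did fry (adjusted p = 0.168). No member passed over all genes or adjusted over the list alone. Esrrb reached 10.2 ± 1.61 against 6.90 ± 4.93 CPM and Esrrg 197 ± 41.9 against 127 ± 41.5 CPM (SD, n = 5 each), and in males alone the log2 fold change of Esrrb was -0.027.

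**Figure D2:**
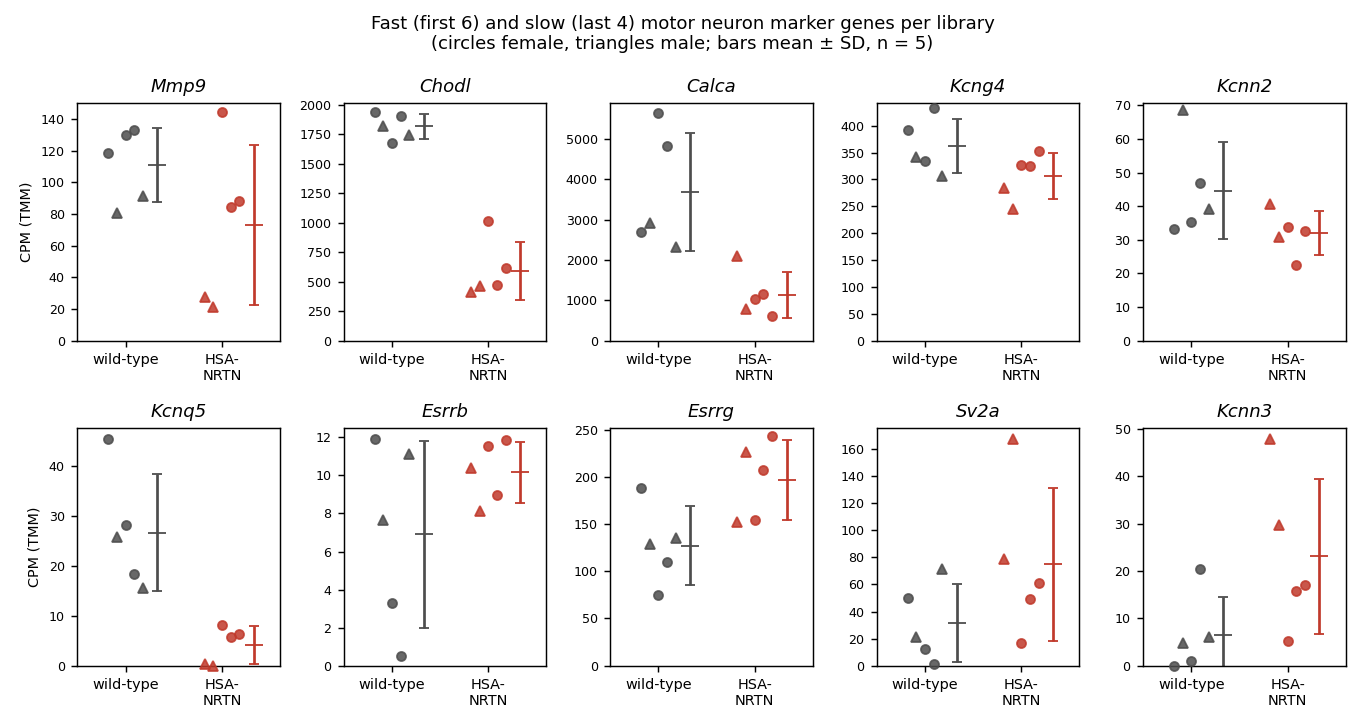
Level of 6 fast and 4 slow motor neuron marker genes in each library, in CPM scaled by TMM, with wild-type libraries in grey and HSA-NRTN libraries in red, circles for females, triangles for males and bars for the mean ± SD (n = 5). Chodl, Calca and Kcnq5 do not overlap between the groups, with Chodl between 408 and 1011 CPM in HSA-NRTN libraries and between 1678 and 1937 CPM in wild-type libraries.

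The wider set of motor neuron identity and cholinergic genes did not move one way. Of 19 measured members 12 had a positive and 7 a negative log2 fold change (median 0.21, camera adjusted p = 0.404), while fry's test for changes in either direction gave an adjusted p of 0.000334. None passed over all genes, and adjusted over the list alone 3 rose, 2 fell and 14 did not pass. Ret, the tyrosine kinase receptor of GDNF family ligands, rose 2.03-fold, from 420 ± 72.5 to 852 ± 325 CPM (SD, n = 5 each), Anxa4, an annexin, rose 2.72-fold and Uts2b, a urotensin peptide gene, 2.32-fold. Calca and its paralog Calcb fell, the latter from 804 ± 359 to 415 ± 137 CPM, and reads shared between the 2 paralogs were not separated here. Chat, the enzyme of acetylcholine synthesis, was at 117 ± 20.2 against 89.5 ± 11 CPM (SD, n = 5 each), a difference that did not pass (log2 fold change 0.38, SE 0.22). Of the alpha motor neuron markers, adjusted over the list alone the peptide receptor gene Vipr2 fell (log2 fold change -0.83, SE 0.28), while Rbfox3 (-0.54, SE 0.27) and Spp1 (0.80, SE 0.34), which encodes osteopontin, did not pass. The 3 measured gamma motor neuron markers, Esrrg, Htr1f and Gfra1, had positive log2 fold changes and did not pass, and that of Gfra1, 0.22 (SE 0.42), turned to -0.029 without HSA-NRTN replicate 4. Both lists were too small for camera.

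In the list of GDNF family ligands and receptors, all 5 measured members had a positive log2 fold change (median 0.38, camera adjusted p = 0.0683, which did not pass). The list passed without HSA-NRTN replicate 2 (0.0233), HSA-NRTN replicate 3 (0.0128), wild-type replicate 2 (0.0303) or wild-type replicate 4 (0.0378), with sex (0.0224) or the runs of animal numbers (0.0238) as a covariate, and without both HSA-NRTN replicate 2 and wild-type replicate 1 (0.0444), but not with an estimated correlation (0.341) or by fry (0.189). Adjusted over the list alone Ret rose and the other 4 did not pass. Gfra2, the preferred co-receptor of neurturin, had 0 counts in all HSA-NRTN libraries and 50 counts spread over 3 wild-type libraries, and was removed by the filter of the main fit. In the authors' deposited DESeq2 table its adjusted p was 0.519. Nrtn was near the limit of detection, with 15 counts in HSA-NRTN and 9 in wild-type libraries. Among 14 measured genes of other neurotrophic factors and receptors (median -0.07, camera adjusted p = 0.924), 1 rose when adjusted over the list alone, the growth factor gene Bdnf, from 8.41 ± 5.06 to 56.2 ± 28.8 CPM (SD, n = 5 each), and 13 did not pass. The median log2 fold change and the mean of that list, 0.03, differed in sign. Of 17 measured immediate early and RET/ERK response genes, 15 had a positive log2 fold change (median 0.45, camera adjusted p = 0.0689) and no member passed. This list passed without wild-type replicate 1 (0.0398), HSA-NRTN replicate 3 (0.0128), wild-type replicate 2 (0.0294), HSA-NRTN replicate 4 (0.00803) or wild-type replicate 5 (0.0135). It also passed with sex (0.0218) or the number of genes detected (8.48e-05) as a covariate, but not with an estimated correlation (0.720) or by fry (0.668). Fos was at 29.4 ± 12.9 against 15.7 ± 3.97 CPM. Over the panel of 15 genes chosen for the theme of the series, 13 were measured, none passed over all genes, and adjusted over the list alone Ret rose and Chodl and Calca fell.

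Neither list of nuclear genes of oxidative phosphorylation passed. The median log2 fold change was 0.00 over 37 genes of complex I (camera adjusted p = 0.726) and 0.02 over 40 genes of complexes II to V (adjusted p = 0.966), and none of either list had an unadjusted p under 0.05 in edgeR. Both lists turned to a called lower level with the number of genes detected as a covariate (adjusted p = 0.00349 and 0.00661), and to a called higher level with the runs of animal numbers as a covariate (adjusted p = 0.0106 and 0.0397), and did not pass with an estimated correlation (0.939 and 0.989) or by fry (0.941 and 0.965). The mitochondrially encoded mRNAs were lower as a group, with 11 of 12 measured members negative and a median log2 fold change of -0.35 (camera adjusted p = 0.00281), but not with an estimated correlation (adjusted p = 0.720). None of the 12 passed over all genes or adjusted over the list alone. The subunit gene mt-Nd5 was at 1720 ± 275 against 2806 ± 815 CPM and mt-Atp6 at 47.6 ± 21.8 against 105 ± 65.6 CPM (SD, n = 5 each), and both overlap other mitochondrial genes. The mitochondrial share of counts was highest in wild-type replicate 1, at 12.9%, and HSA-NRTN replicate 2, at 11.9%. The call ended without wild-type replicate 1 (adjusted p = 0.216) or HSA-NRTN replicate 4 (adjusted p = 0.144), and the direction turned with the number of genes detected as a covariate (adjusted p = 0.971).

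**Figure D3:**
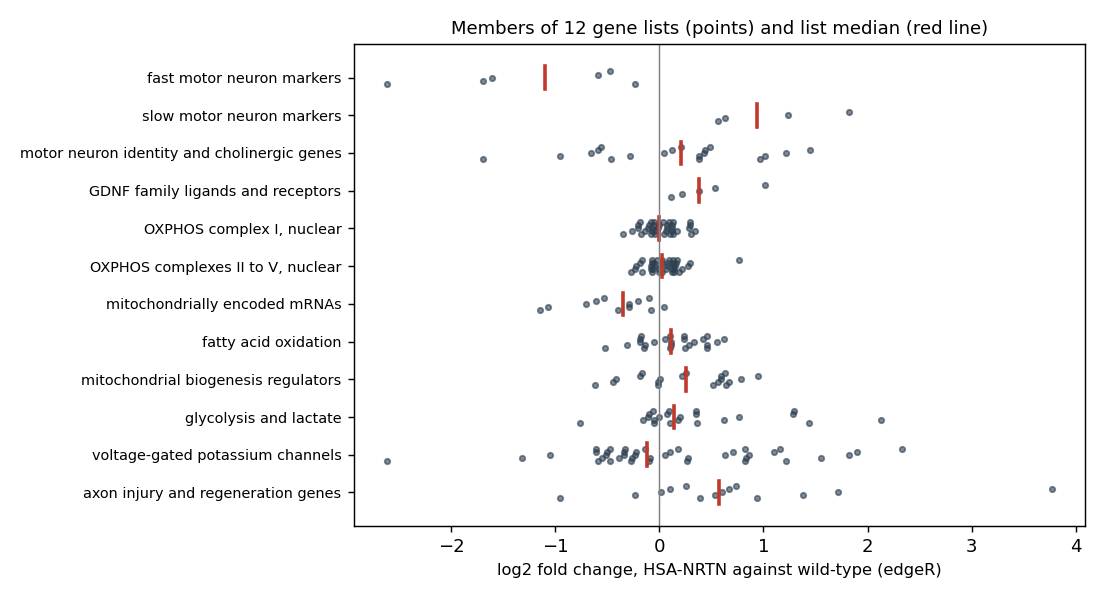
Log2 fold change of each measured member of 12 gene lists, HSA-NRTN against wild-type pools (edgeR), with a red line at the list's median. The 6 fast motor neuron markers lie below 0 with a median of -1.10, and the 4 slow motor neuron markers above 0 with a median of 0.93.

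No other list of energy metabolism passed with all libraries. Of 28 measured genes of the TCA cycle and pyruvate oxidation, 18 had a positive log2 fold change (median 0.08, camera adjusted p = 0.404), with Pdk2, a kinase that inhibits pyruvate dehydrogenase, at 55.1 ± 11.8 against 34.6 ± 11.2 CPM (SD, n = 5 each). Of 24 genes of fatty acid oxidation, 16 were positive (median 0.11, adjusted p = 0.404). Of 19 mitochondrial biogenesis regulators, 12 were positive (median 0.26, adjusted p = 0.0689), among them the coactivator gene Ppargc1a, at 54.5 ± 8.08 against 34.4 ± 21.6 CPM, whose log2 fold change of 0.67 (SE 0.43) was -0.19 in males alone. Of 22 genes of glycolysis and lactate, 14 were positive (median 0.14, adjusted p = 0.385), with the glucose transporter gene Slc2a1 2.45-fold higher and the enolase gene Eno1, which has near-identical pseudogenes, at 60.7 ± 52.1 against 25.0 ± 11.9 CPM. Without HSA-NRTN replicate 4 the log2 fold change of Eno1 fell from 1.29 to 0.66. The aldolase gene Aldoc was 1.70-fold higher. The lactate transporter gene Slc16a7 had a log2 fold change of 2.13 (SE 0.94), and one of 3.01 without wild-type replicate 2. In these 4 lists no member passed over all genes or adjusted over the list alone. The mitochondrial biogenesis regulators passed as a list without wild-type replicate 1 (0.0325), HSA-NRTN replicate 3 (0.0314), wild-type replicate 2 (0.0144) or HSA-NRTN replicate 5 (0.0475). Glycolysis and lactate passed without HSA-NRTN replicate 3 (0.0277). Without both HSA-NRTN replicate 2 and wild-type replicate 1, the mitochondrial biogenesis regulators (0.0394) and the TCA cycle and pyruvate oxidation (0.0444) passed. With an estimated correlation and by fry the regulators did not pass (0.341 and 0.168), nor did glycolysis and lactate or the TCA cycle (0.922 and 0.732 each).

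Ion channel genes went both ways. Of 40 measured voltage-gated potassium channel genes, 18 had a positive and 22 a negative log2 fold change (median -0.12, camera adjusted p = 0.435; fry for changes in either direction, adjusted p = 0.00582), and adjusted over the list alone 2 rose, 1 fell and 37 did not pass. Kcnq3 rose from 13.3 ± 8.65 to 66.7 ± 37.9 CPM (SD, n = 5 each) and Kcnb2 2.15-fold, while Kcnq5 fell. The channel subunit gene Kcnmb4, with a log2 fold change of 1.15 (SE 0.47), did not pass. Of 24 voltage-gated sodium and calcium channel genes (median -0.10, camera adjusted p = 0.404), adjusted over the list alone Cacna2d1 and the sodium channel subunit gene Scn2b rose, the latter from 7.85 ± 5.10 to 36.4 ± 26.0 CPM, and 22 did not pass, with log2 fold changes of -0.92 (SE 0.32) for Scn4b and -2.76 (SE 0.98) for Cacna1e, the latter -4.09 without HSA-NRTN replicate 1. Median and mean, 0.11 for the potassium and 0.08 for the sodium and calcium channels, differed in sign in both lists.

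Receptor genes for synaptic input gave 4 members that passed when adjusted over their list alone, and none over all genes. Of 15 measured cholinergic and monoamine receptor genes (median 0.36, camera adjusted p = 0.174; fry for changes in either direction, adjusted p = 0.0270), 3 rose and 12 did not pass. The serotonin receptor gene Htr1b rose from 13.8 ± 3.77 to 44.2 ± 16.7 CPM (SD, n = 5 each), and the adrenergic receptor genes Adra2a and Adra1b rose 4.74-fold and 4.18-fold, while Adra2c, with a log2 fold change of -1.79 (SE 0.74), did not pass and was at 0.37 in males alone and at -0.46 without wild-type replicate 1, the library of its highest level (82.4 CPM). That of Adra2a was 2.24, and 2.93 without wild-type replicate 5. Of 16 GABA and glycine receptor genes (median -0.18 with a mean of 0.52, camera adjusted p = 0.872), 1 rose, Gabrg3, from 0.648 ± 0.941 to 13.3 ± 11.8 CPM, and 15 did not pass, among them Glra2 at 175 ± 186 against 42.1 ± 28.0 CPM and Glra3 at 8.39 ± 8.46 against 0.670 ± 1.23 CPM. With 1 library left out, the log2 fold change of Gabrg3 was 3.55 without HSA-NRTN replicate 2 and 5.35 without wild-type replicate 4, that of Glra2 1.33 without HSA-NRTN replicate 2, and that of Glra3 2.97 without HSA-NRTN replicate 1 and 5.63 without wild-type replicate 2. With all libraries they were 4.24, 2.04 and 3.66. Of 15 ionotropic glutamate receptor genes (median -0.04 with a mean of 0.12, camera adjusted p = 0.808) none passed, with Gria1 at 29.0 ± 15.8 against 9.88 ± 3.54 CPM. The 33 genes of the presynaptic release machinery (median -0.05 with a mean of 0.18, adjusted p = 0.808) did not pass either, with log2 fold changes of 1.15 (SE 0.43) for Vamp2, 0.54 (SE 0.22) for Syn2, 1.03 (SE 0.42) for Rab3c and 1.77 (SE 0.74) for Syt1, the last at 1.02 without HSA-NRTN replicate 1. None of 29 neurofilament and axonal cytoskeleton genes passed (median -0.03 with a mean of 0.03, adjusted p = 0.123). As a list the cytoskeleton genes passed as lower without HSA-NRTN replicate 1 (0.0143), HSA-NRTN replicate 2 (0.0407), HSA-NRTN replicate 5 (0.0475) or wild-type replicate 3 (0.0242). The cholinergic and monoamine receptors passed as higher without HSA-NRTN replicate 3 (0.0128) or wild-type replicate 2 (0.0303), or with sex as a covariate (0.0492). With an estimated correlation and by fry neither the cytoskeleton genes (0.720 and 0.732) nor these receptors (0.720 and 0.392) passed.

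Genes of axon injury and regeneration were positive in 12 of 14 measured members (median 0.57, camera adjusted p = 0.123), with 1, Cacna2d1, that rose when adjusted over the list alone and 13 that did not pass, among them the endopeptidase gene Ecel1, with a log2 fold change of 1.38 (SE 0.52), and of 0.75 without HSA-NRTN replicate 1. Without HSA-NRTN replicate 3 the list of axon injury and regeneration genes passed (adjusted p = 0.00244), as it did with sex (0.00930) or the number of genes detected (0.00215) as a covariate, but not with an estimated correlation (0.720) or by fry (0.693). No member passed in the lists of the unfolded protein and integrated stress response (27 measured, median 0.07, adjusted p = 0.447), heat shock genes (18, median 0.08, adjusted p = 0.808), proteasome subunits (31, median 0.01, adjusted p = 0.808), cytosolic ribosomal proteins (78, median 0.08, adjusted p = 0.247), mitochondrial ribosomal proteins (75, median -0.04 with a mean of 0.01, adjusted p = 0.424) and cholesterol synthesis (22, median 0.15, adjusted p = 0.306). The ribosomal protein gene Rpsa, which has near-identical pseudogenes, had a log2 fold change of 0.95 (SE 0.38) and the mitochondrial ribosomal protein gene Mrps2 one of -0.66 (SE 0.28). In all, camera with its preset correlation called 3 of 31 lists, and camera with an estimated correlation and fry called 1 each, the fast motor neuron markers. Cytosolic ribosomal proteins passed as a list without wild-type replicate 3 (0.0464) or 4 (0.0158). Mitochondrial ribosomal proteins passed without wild-type replicate 4 (0.0378). With the runs of animal numbers as a covariate both cytosolic (0.0397) and mitochondrial ribosomal proteins (0.0117) passed as higher. With the number of genes detected as a covariate mitochondrial ribosomal proteins (0.00215) and proteasome subunits (0.000635) passed as lower. None of these 3 lists passed with an estimated correlation (0.939 each) or by fry (0.826 to 0.941). With 1 library left out, the count of called lists was 10 without HSA-NRTN replicate 3, 8 without wild-type replicate 2, 7 without wild-type replicate 1 or 4, 6 without HSA-NRTN replicate 2 or wild-type replicate 3, 5 without HSA-NRTN replicate 5 or wild-type replicate 5, 4 without HSA-NRTN replicate 1 and 3 without HSA-NRTN replicate 4.

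No list of markers of other spinal cord cells passed without a covariate in all 10 libraries. Camera gave an adjusted p of 0.808 for 9 measured astrocyte markers (median log2 fold change -0.03 with a mean of 0.33), 0.62 for 13 oligodendrocyte and myelin markers (median 0.43), 0.304 for 4 microglia and macrophage markers (median -0.08 with a mean of 0.16) and 0.808 for 4 inhibitory interneuron markers (median -0.03 with a mean of 0.13), and no member of these lists passed. The oligodendrocyte and myelin markers passed as higher with the number of genes detected as a covariate (0.00215) and without wild-type replicate 1 (0.0398), and turned to lower with the runs of animal numbers as a covariate (0.509). They did not pass with an estimated correlation (0.939) or by fry (0.941). Lists of too few measured members for camera were those of oligodendrocyte precursors (2 measured, median 0.47), endothelial cells and pericytes (2, median 1.54), excitatory interneurons (2, median 0.03), meninges and fibroblasts (3, median 0.47 with a mean of -0.40), blood cells (2, median 1.13), Schwann cells (1, at 0.12) and skeletal muscle (none measured). Of their members, the pericyte gene Rgs5 passed when adjusted over the list alone, at 19.8 ± 29.2 against 3.42 ± 3.95 CPM (SD, n = 5 each), and its highest level, 71.9 CPM, was in HSA-NRTN replicate 2. Its log2 fold change was 0.98 without that library and 3.41 without wild-type replicate 1. In that library the summed oligodendrocyte markers stood at 3.98, the astrocyte markers at 1.96 and the endothelial markers at 5.55 times the median of the other libraries, as ratios of summed CPM. The ratio was 0.689 for Schwann cell, 1.02 for excitatory interneuron, 1.26 for skeletal muscle and 1.45 for meningeal and fibroblast markers, each highest in another library. For oligodendrocyte precursor (3.88), microglia and macrophage (3.12), blood cell (6.08) and inhibitory interneuron markers (2.06) it was highest in HSA-NRTN replicate 2.

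The comparison of male with female pools, with genotype in the model, checks the sex labels. Xist, the RNA that silences an X chromosome, fell by 8.12 on the log2 scale (SE 0.69, edgeR adjusted p = 8.64e-05), from 70.7 ± 30.1 CPM in 6 female to 0.219 ± 0.283 CPM in 4 male libraries (SD), and was the 1 gene called, beside 1302 genes with an unadjusted p under 0.05. The Y-linked genes were removed by the filter set for the genotype groups. With a filter set for the sexes, chosen after seeing the data, 5 genes were called, Xist and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d. Ddx3y, an RNA helicase gene, had 196 to 877 counts in male and 0 to 2 counts in female libraries, so the sex labels matched in all 10 libraries. DESeq2 called 205 genes with its own filtering and 105 on the genes kept for edgeR. Some of the 205 had log2 fold changes of 18.6 to 19.3, against 10.4 for Ddx3y, and such sizes are not read as sex differences here. Gad2 was also called, at 38.9 and 53.0 CPM in male HSA-NRTN but 1.98 and 8.13 CPM in male wild-type libraries. Leaving out wild-type replicate 1 raised the count in edgeR to 176. In the libraries then left, the mitochondrial share was 6.97% to 11.9% in males and 4.15% to 6.24% in females. Sex and library quality cannot be told apart in that count. Leaving out HSA-NRTN replicate 3, 4 or 5 or wild-type replicate 3 or 4 raised the count in edgeR to 5. These are female libraries. Without 1 of them its group held 4 libraries, and the filter goes by the smallest group. Y-linked genes seen in the 4 male libraries could then enter the test.

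The interaction of genotype and sex asks whether the genotype effect differed between males and females. The edgeR quasi-likelihood test called 0 genes, with 598 at an unadjusted p under 0.05, and DESeq2 called 16 with its own filtering and 8 on the genes kept for edgeR. With 2 males in each group, the simulated data showed 0% of interactions of 2-fold and of 4-fold recovered and 15.2% of those of 8-fold, so smaller differences between the sexes were not detectable at this size.

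No difference in library quality between the groups passed. In exact two-sided permutation tests over all assignments, where the smallest possible p is 0.00794, p was 0.532 for the gene count, 0.238 for the genes detected, 0.548 for the mitochondrial share and 0.516 for the share of the 20 largest genes, each with an adjusted p of 0.548. Genes detected averaged 17199 in HSA-NRTN and 15753 in wild-type libraries. Spearman correlations across genes between libraries, where genes are not independent replicates, ran from 0.736 to 0.820 for pairs with HSA-NRTN replicate 2, from 0.775 to 0.837 for pairs with wild-type replicate 1, and from 0.823 to 0.948 among the other 8 libraries.

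The authors' deposited table of the same comparison called 154 genes, 111 higher and 43 lower in HSA-NRTN pools. Of the 95 deposited calls on genes tested here, all 95 had the same sign in edgeR, 93 had an unadjusted p under 0.05, 9 an adjusted p under 0.1 and 1, Ptpro, passed. In the authors' deposited table the log2 fold change was 2.69 for Ptpro, -1.52 for Chodl, -1.42 for Calca, 0.90 for Ret and 1.88 for Bdnf, on a moderated scale. Fold changes in edgeR and in the authors' deposited table had a Pearson r of 0.934 and a Spearman rho of 0.976 across 11630 genes, which are not independent replicates. Of the deposited calls, 17 had over 90% of their CPM in 1 library, HSA-NRTN replicate 2, and all 17 were higher calls.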

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

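The tests of the share of motor neuron RNA, of RNA of other cell types and of the splits for the slow markers, and the value without both libraries that stood apart, were chosen only after the result was seen.

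Of 67 groups of 5 libraries checked for a library far from the others, 6 held one, where chance gives 3.35 if values are normally spread. CPM of low genes are not, so 3.35 is only a rough guide. Hrk in HSA-NRTN libraries had a gap of 0.871 of the group's range, with HSA-NRTN replicate 2 at 33.5 CPM and the others at 2.20 to 6.23 CPM. Hrk in wild-type libraries had a gap of 1, from the single count of wild-type replicate 5, which any count there beside zeros would give. Pnoc in HSA-NRTN libraries had a gap of 0.774, with HSA-NRTN replicate 2 at 68.1 CPM and the others at 3.48 to 18.1 CPM. Nrtn in HSA-NRTN libraries had a gap of 0.796, with replicate 5 at 1.48 CPM and the others at 0.366 to 0.593 CPM. Gfra2 in wild-type libraries had a gap of 0.740, with replicate 3 at 7.27 CPM and the others at 0 to 1.89 CPM. Chat in wild-type libraries had a gap of 0.738, with replicate 4 at 70.7 CPM and the others at 90.9 to 98.1 CPM.

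Fast motor neuron markers were lower in HSA-NRTN pools. Of 100 splits of the libraries 1, the real one, gave a camera p as small as 8.18e-11. The smallest of the others was 1.70e-07. That is the smallest share 100 splits can give, and it is not adjusted for the 31 lists or the other tests by splits. The splits kept to neither sex nor the runs of animal numbers, so chance is not firmly excluded. A lower share of motor neuron RNA would pull identity genes down alike, but 18 identity genes outside the list had a mean log2 fold change of 0.20 (SE 0.16) against -1.21 (SE 0.38) for the fast list, a difference of 1.41 (SE 0.41). These SE were taken across genes measured in the same libraries, so they do not measure the spread between animals. The list kept its call with the number of genes detected as a covariate (adjusted p = 4.36e-08) and without both libraries that stood apart (adjusted p = 2.11e-07), over a range of 1.47e-10 to 0.0368 in all alternatives, which argues against library complexity or these libraries as the whole cause. A lower level per cell and fewer fast cells among those captured stay open, since pools do not tell them apart, and neither was tested. For the slow markers 3 of 100 splits gave a p as small (0.000256, with 1.64e-05 as the smallest of the others), beside a call that an estimated correlation ended.

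Counts of many genes were found mainly in HSA-NRTN replicate 2, where 98 genes had over 90% of their CPM and 210 genes had at least 10 counts in no other library, against at most 15 and 40 in any other library. A loss of molecules in a library of low yield goes with 83 genes at 0 counts there that all other libraries held at 10 counts or more, against 36 in wild-type replicate 1 and at most 6 elsewhere. HSA-NRTN replicate 2 had the lowest gene count, which can add zeros, but gene count alone did not order them. Wild-type replicate 1 had 36 such zeros at 4935435 gene counts, and HSA-NRTN replicate 1 had 4 at 3257700. Genes lost in HSA-NRTN replicate 2 also do not account for genes found mainly there, so the zeros do not decide the cause. RNA of other cell types stays open as the cause for the genes found mainly there. Of 95 marker genes 33.7% had their highest level in this library, between the bounds set for and against it. That share pools cell types that differed. Highest here were 11 of 16 oligodendrocyte and myelin markers and 8 of 14 astrocyte markers. These counts go with RNA of these 2 cell types in this library. Of microglia and macrophage markers 2 of 15 were highest here, and of Schwann cell markers 0 of 3. Mobp of myelin was at 150 CPM against 2.97 to 24.0 CPM in the others. The astrocyte transporter gene Slc1a2 was at 665 CPM against 21.2 to 215 CPM. Schwann cell, excitatory interneuron, skeletal muscle and meningeal markers were in sum highest in other libraries. Capture took cells one by one under the microscope, which would leave out most of such cells but not processes attached to them. No biological explanation was tested.

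The number of genes called by genotype was reached in 3 of 100 splits, the real one included (1 in the real split, 5 as the highest of the others). This lay under the bound of 5 in 100 set beforehand. It rests on a count of 1 gene, which fell to 0 with the runs of animal numbers as a covariate or without wild-type replicate 2. The splits did not keep to these runs, so chance is not firmly excluded. The number of lists called was reached in 79 of 100 splits (3 in the real split, 17 as the highest of the others), so chance cannot be excluded for that count. The number of genes called by sex was reached in 7 of 100 splits into 4 and 6 libraries, with 1 in the real split and 258 as the highest of the others, so by this count chance cannot be excluded. These splits are not free of sex, and the filter set for the genotype groups held the real count low, so the comparison says little about the sex difference itself. Counts of 258, 201 and 72 genes in 3 of the other splits point to a structure of the samples. The 258-gene split set apart HSA-NRTN replicate 2 and wild-type replicates 1, 2 and 5. These had the highest mitochondrial shares (8.12% to 12.9%) and the fewest genes detected (14090 to 15843). The 201-gene split set apart replicates 3 and 4 of both groups, with the lowest shares of reads not aligned (16.3% to 29.1%). These 2 splits thus go with measures of library quality, while the 72-gene split followed none of these measures exactly. They also go with sex. The 258-gene side held male libraries beside the female wild-type replicate 1, and the 201-gene side was all female. The 72-gene side held the males HSA-NRTN replicates 1 and 2 and wild-type replicate 5, beside wild-type replicate 1. Sex and library quality cannot be told apart in these counts.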

How the results depend on the processing

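The values of the adjusted-deviance fit, robust shrinkage, an adjusted p under 0.1, 8 libraries, the filter set for the sexes and DESeq2 on the genes kept for edgeR come from tests chosen only after the data were seen. Unless a cause is named, the cause was not tested.

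Against 1 gene called by genotype, the count was 1 with RLE or upper quartile factors and with the stricter filter, 81 with no filter beyond 1 count (64 higher, 17 lower), 126 in DESeq2 with its own filtering on all genes with a count and 59 in DESeq2 on the genes kept for edgeR, 3 in limma voom, 12 in limma voom with sample quality weights (all lower), 5 with sex, 0 with the runs of animal numbers and 10 with the genes detected as covariates, 0 in females and 0 in males. It was 17 with the adjusted-deviance fit (9 higher, 8 lower), 9 with robust shrinkage and 9 at an adjusted p under 0.1. With 1 library left out it ran from 0 (without wild-type replicate 2) to 13 (without HSA-NRTN replicate 3, the HSA-NRTN library nearest to the wild-type libraries). In 8 libraries 1 gene was called, Sln, with 0 shared. Fewer samples alone lower the power in a single sex. Of 62 named genes with a fitted value 58 had 1 direction in all alternatives, 21 were called in at least 1, and over 1602 gene alternatives 1482 kept direction and call, 107 were newly called, 7 no longer called and 6 turned. Gfra1 turned to -0.18 with the genes detected as a covariate, to -0.054 in males and, with 1 library left out, ran from -0.029 (without HSA-NRTN replicate 4) to 0.65. In males Esrrb turned to -0.027, Ppargc1a to -0.19 and Adra2c to 0.37.

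Against 3 lists called, the count was 1 with an estimated correlation, 1 by fry, 7 with sex, 8 with the runs and 9 with the genes detected as covariates, 8 in 8 libraries and from 3 (without HSA-NRTN replicate 4) to 10 (without HSA-NRTN replicate 3) with 1 library left out. Fast motor neuron markers kept direction and call in all 18 alternatives, with adjusted p from 1.47e-10 to 0.0368. Slow motor neuron markers lost the call with an estimated correlation (adjusted p = 0.270) and by fry (0.168) and kept it with 1 library left out (0.000264 to 0.0378). With the genes detected as a covariate, the direction turned for other neurotrophic factors (adjusted p = 0.133), OXPHOS complex I (0.00349), OXPHOS complexes II to V (0.00661), mitochondrially encoded mRNAs (0.971), the TCA cycle (0.971), neurofilaments (0.628), presynaptic release (0.244), potassium channels (0.189), sodium and calcium channels (0.628), GABA and glycine receptors (0.127), proteasome subunits (0.000635), cytosolic (0.189) and mitochondrial ribosomal proteins (0.00215). With the runs it turned for glutamate receptors (0.939), GABA and glycine receptors (0.820), astrocyte (0.505), oligodendrocyte (0.509) and inhibitory interneuron markers (0.939). By fry it turned for other neurotrophic factors, presynaptic release and glutamate receptors (0.965 each) and GABA and glycine receptors (0.941), the last also with the stricter filter (0.949), and for other neurotrophic factors with sex (0.987).

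With 1 library left out the direction turned at least once in these lists, with adjusted p ranging from 0.450 to 0.931 for other neurotrophic factors, 0.0787 to 0.917 for OXPHOS complex I, 0.0781 to 0.917 for OXPHOS complexes II to V, 0.449 to 0.999 for presynaptic release, 0.676 to 0.994 for GABA and glycine receptors, 0.742 to 0.979 for heat shock genes, 0.110 to 0.979 for proteasome subunits, 0.0378 (without wild-type replicate 4) to 0.999 for mitochondrial ribosomal proteins, 0.515 to 0.931 for astrocyte, 0.0398 (without wild-type replicate 1) to 0.812 for oligodendrocyte and 0.422 to 0.985 for inhibitory interneuron markers.

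Against 1 gene called by sex, the count was 205 in DESeq2 with its own filtering and 105 on the genes kept for edgeR, 5 with the filter set for the sexes and from 1 to 176 (without wild-type replicate 1) with 1 library left out. Without wild-type replicate 1 all male libraries had a higher mitochondrial share than all female libraries. The count of 176 therefore cannot be credited to sex alone. Against 0 genes with an interaction in edgeR, where 598 had an unadjusted p under 0.05, DESeq2 called 16 with its own filtering and 8 on the genes kept for edgeR. Shared calls with the authors' deposited table rose from 1 to 9 at an adjusted p under 0.1 in both and to 104 with DESeq2 here, which also had its own filtering. The quality comparison kept its side of the threshold throughout. No paired analysis was possible because the replicate numbers name no pairs. Depth limits the low genes, many of which rest on counts in a few libraries.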

Other observations

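The tests of a wrong label and of mixed male RNA, and the bounds with 1 library left out, were chosen only after the result was seen.

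Several genes were seen in HSA-NRTN libraries and hardly at all in wild-type libraries. With at least 10 counts in at least 4 libraries of a group and 0 counts in the whole other group, 5 genes were seen in HSA-NRTN libraries alone and 1 in wild-type libraries alone, a total that 5 of 126 splits reached, the real one included, with 9 as the highest of the others. That lies under the level of 0.05 for the total, without adjustment for the other tests by splits. Among the other splits, the highest number of such genes in 1 direction was 8. Chance is therefore not excluded for single genes. Sln, which encodes sarcolipin, a regulator of the calcium pump, was at least 187-fold higher, Htr1d, a serotonin receptor gene that marks gamma motor neurons, at least 42.7-fold, Acpp, an acid phosphatase gene, at least 56.4-fold, Pter at least 41.9-fold and Ppp1r26 at least 23.6-fold. Lum, the gene of the matrix proteoglycan lumican, was at least 32.5-fold lower. The somatostatin gene Sst had 475 counts over all 5 HSA-NRTN libraries and 0 in wild-type libraries (at least 167-fold higher). HSA-NRTN replicate 1 held 395 of them and HSA-NRTN replicate 2 held 37. The inhibitory interneuron gene Gad2 was highest in the same libraries, at 38.9 and 53.0 CPM against 0 to 8.13 CPM in the others. Slc6a5, also of inhibitory interneurons, was highest in wild-type replicate 1 (146 CPM). Interneuron RNA as a source of the Sst counts was not tested. The transthyretin gene Ttr had 426 counts over 4 HSA-NRTN libraries and 0 in wild-type libraries (at least 150-fold higher), with 295 of them in HSA-NRTN replicate 4. With 1 library left out, the lowest bound was 109-fold for Sln, which had 321 of its 530 counts in HSA-NRTN replicate 4, and 25.5-fold for Htr1d, with 72 of 121 counts in the same library. It was 68.2-fold for Ttr without HSA-NRTN replicate 4, 33.4-fold for Sst without HSA-NRTN replicate 1, 37.4-fold for Acpp without HSA-NRTN replicate 2 and 28.2-fold for Pter without HSA-NRTN replicate 5. It was 21.6-fold for Ppp1r26 without HSA-NRTN replicate 3 and 27.0-fold for Lum without wild-type replicate 4. Such bounds cover counting error only.

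Of the gamma motor neuron markers too low to be fitted, Npas1, a transcription factor gene, was at 7.23 ± 5.61 CPM in HSA-NRTN and 0.182 ± 0.261 CPM in wild-type libraries (SD, n = 5 each), with all 5 HSA-NRTN libraries above all wild-type libraries. Wnt7a was at 7.61 ± 9.38 against 0.787 ± 1.15 CPM, with 3 HSA-NRTN libraries above all wild-type libraries. Both were removed by the filter in edgeR. DESeq2 called Npas1 (adjusted p = 0.00162) and Htr1d (adjusted p = 0.000165), edgeR with no filter beyond 1 count called Htr1d (adjusted p = 0.0364), and no alternative called Wnt7a. Capture above a size minimum would leave out most gamma motor neurons.

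HSA-NRTN replicate 3 lay nearest to the wild-type libraries. On 100 genes chosen without it, its median position between the wild-type mean at 0 and the HSA-NRTN mean at 1 was 0.466, above the highest wild-type library at 0.307 and below the other HSA-NRTN libraries at 0.807 to 1.02, which argues against a wild-type library under a wrong label. Its summed Y-linked counts were 0% of the mean of the male libraries, which argues against RNA of male wild-type cells. RNA of female wild-type cells and a weaker response of that animal were not tested.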
